A study of Homo sapiens with 6 samples.

How the data were processed

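The comparison was between 3 libraries of ABCA3:GFP-positive and 3 libraries of ABCA3:GFP-negative cells, sorted on day 31 from differentiations of 1 human iPSC line. The labels call them biological triplicates and also speak of triplicate wells and triplicate differentiations, so the p-values measure the spread between cultures of 1 line, not between donors. Per the labels' protocols, poly(A) RNA was fragmented, reverse transcribed and sequenced on a NextSeq 500, read quality was checked with FastQC 0.11.7, reads were aligned with STAR to the human genome joined with the GFP reporter sequence, and reads per gene were summed with featureCounts of Subread 1.6.2. The sources differ on the alignment: the labels' protocols name STAR 2.6.0c and a build written GRCh39, whereas STAR 2.5.2b and GRCh38 stand in the submitters' processing notes. The submitters' processing notes also list edgeR 3.25.10 without saying what it was used for. Whether the counting used strand is not given in the sources used here, so overlapping genes on opposite strands cannot be told apart.

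The deposited values are FPKM, fragments per kilobase of exon scaled to the size of the library, for 27980 genes in 6 columns. Gene coordinates and exon lengths came from GENCODE 29 (GRCh38), in which 21162 genes matched by name, 6717 by identifier and 101 not at all. FPKM times the joint exon length came in whole multiples of 1 step per library: with a tolerance of 0.02 and values up to 1000 reads, 97.8% of values were whole in each library, and 27397 genes (97.9%) were whole in all 6. The reads recovered in this way sum to 46239133 to 53018195 per library. The library size behind the deposited FPKM was another number, 45724349 to 58471258, so that the recovered sum was 108% to 111% of it in GFP-positive and 90.0% to 92.8% in GFP-negative libraries; the deposited FPKM were therefore divided by an adjusted library size and not by the plain total. The columns sum to 329527 to 341694 FPKM in GFP-positive and 250403 to 257601 in GFP-negative libraries. The 10 most abundant genes took 11.2% to 11.9% of the reads in GFP-positive and 7.79% to 7.93% in GFP-negative libraries. No 2 replicates agreed within sampling noise: the median chi-square per gene of the recovered reads was 1.15 to 2.88 between replicates of a group, where sampling alone gives 0.455.

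The test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend in the prior variance) on log2(FPKM + 1) as deposited, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, for 13445 genes with an FPKM of at least 1 in at least 3 libraries. Every log2 difference is GFP-positive minus GFP-negative on this scale, which understates the change of genes of low FPKM; ratios are of mean FPKM. Errors are SDs over 3 libraries for FPKM and standard errors from limma for log2 differences, and every adjusted p of a gene is from limma. A count test was not used, because the deposited unit is FPKM. Gene lists (30, chosen from textbook knowledge) were tested with camera in limma at its preset inter-gene correlation of 0.01 where at least 5 members were tested, which held for 26 lists, with adjustment over those lists. Camera with an estimated correlation and fry were alternatives; fry asks whether the members of a list move, on balance, one way and does not compare them with other genes. The test, the groups, the lists, the rule for named genes and the alternatives were fixed before the data were examined.

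Genes were named by a rule: ABCA3 and the reporter; the 10 largest rises and 10 largest falls in log2 difference among genes past the threshold, with a mean of at least 5 FPKM in the higher group, no overlap between the groups and a name that is not that of a clone or uncharacterised locus; and of each list up to 4 members past the threshold with the largest change and up to 2 abundant members that did not pass, fewer where a statement did not need them. Some genes the rule names are not reported here. Genes outside it are said to have been named after their values were seen. Genes of sex chromosome Y and the X-inactivation transcript were left out of naming.

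The test was tried on simulated reads for 12957 genes with 3 libraries a group, drawn from the means and library sizes of this comparison, with known changes. It recovered 31.3% of genes changed 1.25-fold, 79.6% of those changed 1.5-fold, 93.9% at 2-fold and 100% at 4-fold, and 9.64% of its calls, 16 genes, were of unchanged genes, more than the 5% aimed at. Few genes were changed, all genes had the same relative spread, and no scaling shift between the groups was simulated. These shares therefore need not hold for the calls in the real data. In simulated lists, camera called the changed list and 0 of 30 unchanged lists. The simulated genes varied independently of each other, so this does not test the effect of inter-gene correlation on the list calls.

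The alternatives were pseudocounts of 0.1 and 0.5; no filter, a minimum of 5 FPKM or a mean of at least 1 FPKM; libraries scaled to equal FPKM sums or by the median of ratios, or quantile normalized; limma without trend, with a robust prior or with array weights; a replicate block; and leaving out each library in turn. After the data were seen, scaling to the recovered read totals and limma voom on the recovered reads were added. The range given beside a list's adjusted p is over the alternatives that keep camera at its preset correlation, 20 where each left at least 5 members. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.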

Results

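Poly(A) RNA was sequenced from 6 samples of BU3AG23CR6, a human induced pluripotent stem cell (iPSC) line with a green fluorescent protein (GFP) reporter of ABCA3, the transporter that loads surfactant lipid into the lamellar bodies of alveolar type II (AT2) cells. The line had been taken through definitive endoderm, reached by day 3, and anterior foregut endoderm, reached by day 6, to lung progenitors, which were enriched on day 15 by sorting for high CD47 and low CD26. The sorted progenitors grew in Matrigel in a distal lung medium with a WNT pathway activator, keratinocyte growth factor, dexamethasone, cyclic AMP and a phosphodiesterase inhibitor. On day 31 live cells were sorted into an ABCA3:GFP-positive and an ABCA3:GFP-negative population, with 3 libraries of each. The libraries held 49968111 to 53018195 reads in the listed genes in the GFP-positive group and 46239133 to 52613666 in the GFP-negative group, as recovered from the deposited FPKM values. One read on a transcript of 1 kb was worth 0.0171 to 0.0219 FPKM.

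The comparison of GFP-positive with GFP-negative cells asks which genes go with the AT2 reporter in cultures of 1 line. The surfactant protein genes SFTPB and SFTPC were far higher in the GFP-positive cells. SFTPB, the gene of surfactant protein B, stood at 4711 ± 235 FPKM in GFP-positive cells against 11.6 ± 2.49 in GFP-negative cells (SD, n = 3 each), a 407-fold ratio of means. SFTPC, whose product surfactant protein C is specific to AT2 cells, stood at 160 ± 7.54 against 0.694 ± 0.412 FPKM. NKX2-1, the transcription factor of lung epithelial identity, was 7.94-fold higher, at 82.6 ± 3.21 against 10.4 ± 1.68 FPKM. Hepatic and intestinal markers, targets of WNT signalling and targets of BMP and TGF-beta signalling were mostly lower in the GFP-positive cells, among them the plasma protein gene AHSG (1.30 ± 0.459 against 34.6 ± 5.34 FPKM), the hindgut transcription factor CDX2 (1.12 ± 0.0544 against 10.8 ± 0.912) and the WNT effector LEF1 (1.12 ± 0.0143 against 8.49 ± 0.676).

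The reporter and its gene followed the sort. ABCA3 (ENSG00000167972.13, chromosome 16, 2275881 to 2340746, minus strand, GRCh38) stood at 183 ± 2.17 FPKM in GFP-positive and 1.05 ± 0.0197 FPKM in GFP-negative libraries (SD, n = 3 each), a log2 difference of 6.49 (SE 0.03, limma adjusted p = 3.49e-11). The reporter transcript, listed as EGFP, stood at 151 ± 5.13 against 0.546 ± 0.191 FPKM (log2 difference 6.63, SE 0.08). The cells were gated on this reporter, so neither value is a finding between the populations. Every library of one population lay above every library of the other for both genes.

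**Figure D1:**
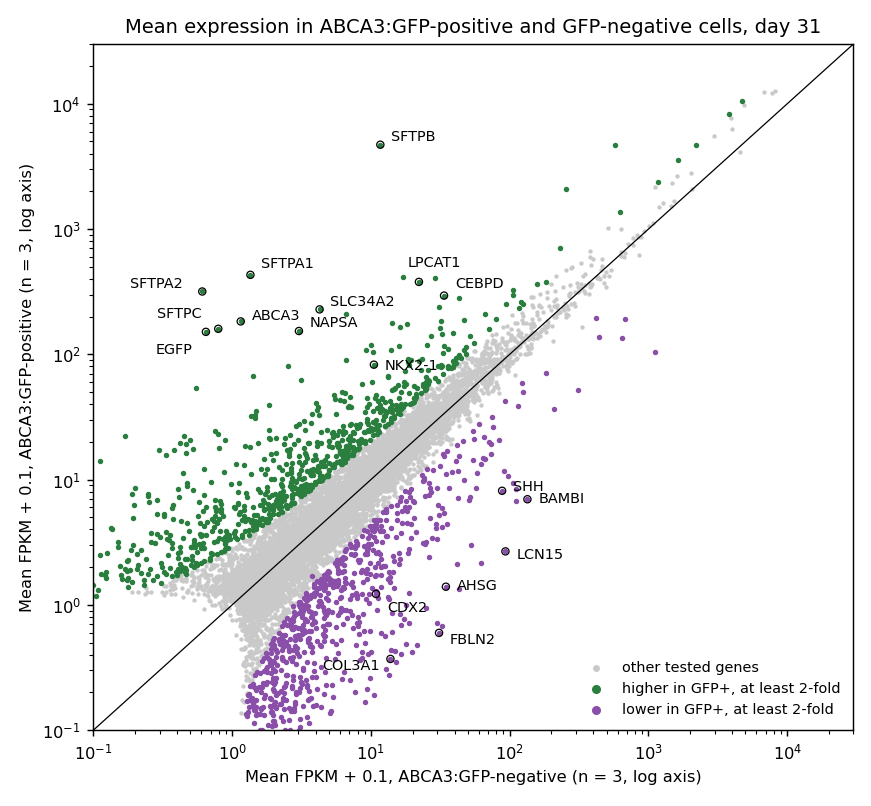
Mean FPKM plus 0.1 of each tested gene in GFP-negative (x axis) and GFP-positive (y axis) libraries, n = 3 each, both axes logarithmic. Green points were at least 2-fold higher and purple points at least 2-fold lower in GFP-positive cells on the log2(FPKM + 1) scale with an adjusted p under 0.05, grey points are the other tested genes, and the line marks equal values; SFTPB, for example, lies at 4711 against 11.6 FPKM.

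Of 13445 genes tested, 1396 changed at least 2-fold on the log2(FPKM + 1) scale with a limma adjusted p under 0.05. GFP-positive cells were higher for 738 of these and lower for 658. On this scale the change was at least 8-fold for 56 genes that were higher and 44 that were lower. These counts depend on the pseudocount, which shrinks changes of genes of low FPKM. A pseudocount of 0.1 gave 1022 genes at least 2-fold higher and 986 lower. Limma voom on the recovered reads, chosen after the data were seen, gave 1046 and 1005. At any size, 4929 genes were higher and 4129 lower, which together is 67.4% of the genes tested. The populations did not overlap for 72.9% of genes, where chance gives 10%. The first principal component held 93.0% of the variance and separated the populations. Pearson's r across genes was 0.993 to 0.995 between libraries of one population and 0.886 to 0.897 between libraries of different ones. How many genes counted as higher or lower depended on the scaling: the median log2 difference of all genes was 0.03 as deposited and −0.30 with libraries scaled to equal FPKM sums. That scaling gave 2110 genes higher and 8678 lower, and scaling to the recovered read totals, chosen after the data were seen, gave a median of −0.18 with 2847 higher and 7135 lower. With these scalings, the genes changed at least 2-fold split into 444 higher and 1009 lower, and 516 higher and 849 lower. Counts and log2 differences under them include the shift of the median of all genes. Median of ratios scaling gave a median of 0.03 with 5067 genes higher and 4050 lower. Quantile normalization gave a median of −0.02 with 4269 higher and 4846 lower.

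The 10 largest rises were mostly genes known from AT2 cells. After SFTPB came the surfactant protein A genes SFTPA2 (log2 difference 7.72, SE 0.08) and SFTPA1 (7.60, SE 0.14), which are near-identical paralogs and may have exchanged reads, so their separate values are uncertain. EGFP, SFTPC (6.60, SE 0.17) and ABCA3 followed. SLC34A2, the apical sodium-phosphate cotransporter of AT2 cells, rose by 5.47 (SE 0.04), and NAPSA, the aspartic protease that processes surfactant protein B, by 5.31 (SE 0.09). B3GNT7, a glycosyltransferase gene, rose by 4.87 (SE 0.10). MIR3677 (5.35, SE 0.31) lies inside a longer noncoding gene next to ABCA3, so its reads cannot be assigned to the microRNA. The largest falls were of LCN15, a lipocalin gene (log2 difference −4.72, SE 0.10), FBLN2, an extracellular matrix gene (−4.41, SE 0.05), and ACKR3, an atypical chemokine receptor gene (−4.40, SE 0.05). They were followed by CAMK2N1 (−4.36), ODAM (−4.29), the natriuretic peptide gene NPPB (−4.20), the BMP pseudoreceptor gene BAMBI (−4.10), AHSG (−3.96), the homeobox gene MSX1 (−3.95) and the growth factor gene IGF2 (−3.86). The limma adjusted p of these 20 genes, which include ABCA3 and the reporter used for the sort, was at most 3.51e-06. Each was higher or lower in 3 of 3 libraries because the naming rule required it.

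Markers of AT2 cells rose as a group. Of 22 tested members, 21 were higher and 1, the transcription factor gene CEBPA (log2 difference −1.47, SE 0.08), was lower, also when adjusted over the list alone. The median log2 difference was 3.39 (camera adjusted p = 2.96e-10). The list lost this call with an inter-gene correlation estimated from the data (adjusted p = 0.252 with an estimated correlation), as did every other list called here. The pepsinogen gene PGC, named after its values were seen, rose by 3.04 (SE 0.14).

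Transcription factors of the lung epithelium were higher in 13 of 19 cases and lower in 3 (median 0.46, camera adjusted p = 0.0191; adjusted p = 0.384 with an estimated correlation). With equal FPKM sums 9 were higher and 9 lower, and with recovered read totals 10 and 6. Relative to the median of all genes, the list median was 0.43 as deposited and 0.37 with equal FPKM sums. CEBPD rose by 3.11 (SE 0.10), NKX2-1 (ENSG00000136352.17, chromosome 14, 36516392 to 36521149) by 2.88 (SE 0.10) and HOPX, also an alveolar type I marker, by 2.84 (SE 0.09). The 3 that fell were CEBPA and, named after their values were seen, the endoderm factor GATA6 (−0.97) and ELF5 (−0.96). FOXA1, a pioneer factor of foregut endoderm, was at 29.2 ± 1.05 against 29.6 ± 0.416 FPKM and did not pass (log2 difference −0.02, adjusted p = 0.662); with equal FPKM sums it was −0.41 against a median of −0.30 for all genes and passed as lower, as it did with recovered read totals (−0.27) and quantile normalization (−0.23). The call of this list ended with only genes of at least 5 FPKM (adjusted p = 0.162) and with quantile normalization (adjusted p = 0.0738), in a range of 5.87e-04 to 0.162 over 20 alternatives. The counts adjusted over the list alone were again 13 and 3.

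Markers of distal lung bud tip progenitors went both ways, with 5 of 15 higher, 9 lower and a median of −0.27 (camera adjusted p = 0.148). CPM, a carboxypeptidase gene used as a surface marker of lung progenitors, rose by 3.22 (SE 0.10) and SOX2 by 1.04. DLK1 fell by 3.49 (SE 0.10), ID2 by 1.97 (SE 0.05), MYCN by 1.86 and SOX9, the bud tip transcription factor, by 1.24; SOX2 and SOX9 were named after their values were seen. Markers of alveolar type I cells were higher in 9 of 15 cases and lower in 3 (median 0.63, camera adjusted p = 0.0781, not past the threshold). The type I list has 20 members, and those not tested were below the FPKM minimum, so the counts do not cover all type I markers. The tight junction gene CLDN18, also counted among the junction genes, rose by 3.60 (SE 0.10) and the water channel gene AQP4 by 1.86 (SE 0.06). SEMA3B fell by 2.23 (SE 0.06), SPOCK2 by 0.62 and AGER, the most used marker of these cells, by 0.21 (SE 0.05), from 5.42 ± 0.0893 to 4.56 ± 0.273 FPKM, the last pair named after their values were seen. The type I list passed as higher under 5 of 20 alternatives: equal FPKM sums (adjusted p = 6.42e-04), recovered read totals (0.00469), no filter (0.0214), quantile normalization (0.0368) and voom (0.0450), in a range of 6.42e-04 to 0.162. The counts of both lists were the same when adjusted over the list alone.

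Most genes of lipid supply and of the organelles that store surfactant were higher. Some lists share members, so their results are not independent: LPCAT1, FASN, CTSH and LAMP3 are also counted among the AT2 markers. Surfactant phospholipid and fatty acid synthesis had 17 of 23 members higher and 6 lower (median 0.67, camera adjusted p = 0.00306; adjusted p = 0.252 with an estimated correlation), and 14 and 6 with equal FPKM sums. LPCAT1, which makes the saturated phosphatidylcholine of surfactant, rose from 22.1 ± 2.10 to 378 ± 7.20 FPKM (SD, n = 3 each), MFSD2A, a lysophospholipid transporter gene, by a log2 difference of 3.91 (SE 0.07), and FASN, the fatty acid synthase gene, by 1.61 (SE 0.04). Cholesterol synthesis and uptake had 17 of 21 members higher and 0 lower (median 0.57, camera adjusted p = 2.20e-05; adjusted p = 0.252 with an estimated correlation), and 12 higher and 4 lower with equal FPKM sums. The late pathway genes SC5D and LSS rose by 1.13 (SE 0.04) and 1.00 (SE 0.04). The early enzyme gene HMGCS1 (0.05, adjusted p = 0.337) did not pass. It turned lower with equal FPKM sums, at −0.35 against a median of −0.30 for all genes, with recovered read totals (−0.21) and with quantile normalization (−0.24). Of 31 lysosome and lamellar body genes, 27 were higher and 2 lower (median 0.68, camera adjusted p = 1.52e-07; adjusted p = 0.252 with an estimated correlation), and with equal FPKM sums 23 and 6. CTSH, a cathepsin gene of surfactant protein processing, rose by 3.57 (SE 0.08), LAMP3, a lamellar body membrane protein gene, by 3.19 (SE 0.05) and NPC2, a sterol carrier gene, by 2.91 (SE 0.03), while GPR137B and CTSL, named after their values were seen, fell by 1.17 and 0.64. The counts of these 3 lists were the same when adjusted over each list alone.

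Genes of protein folding in the endoplasmic reticulum, of inflammation and of antigen presentation were also mostly higher. Of 21 unfolded protein response genes, 20 were higher and 1, SEL1L (−0.31, named after its value was seen), was lower (median 0.59, camera adjusted p = 5.22e-05; adjusted p = 0.345 with an estimated correlation). With equal FPKM sums 12 were higher and 4 lower, and with recovered read totals 14 and 1. Their median was 0.56 above that of all genes as deposited and 0.49 above it with equal FPKM sums. EDEM1 rose by 1.19, the transcription factor gene XBP1 by 1.12 and DDIT3 by 0.93. NF-kB targets had 10 of 15 members higher and 1, the complement gene C3 (−0.50, named after its value was seen), lower (median 0.91, camera adjusted p = 0.00428; adjusted p = 0.252 with an estimated correlation), which became 9 higher and 6 lower with equal FPKM sums and 9 and 5 with recovered read totals. The NF-kB median was 0.88 above that of all genes as deposited and 0.86 above it with equal FPKM sums. ICAM1, a leukocyte adhesion receptor gene, rose by 3.87 (SE 0.11), and the neutrophil chemokine genes CXCL2, CXCL8 and CXCL1 by 2.67, 2.53 and 2.09. TNFAIP3, which restrains NF-kB, was at 12.0 ± 1.20 against 12.2 ± 0.817 FPKM (limma adjusted p = 0.721). It passed as lower with equal FPKM sums (−0.40) and recovered read totals (−0.27), where the median of all genes was −0.30 and −0.18. The list of MHC class II and antigen presentation has 20 members, of which 9 were tested. Most of its class II genes were absent from the data or below the FPKM minimum, so the list says little of class II. Of the 9 tested genes, 8 were higher and CD74, the class II invariant chain gene, fell by 1.47 (SE 0.05). The list median was 1.02 (camera adjusted p = 0.00819, and 0.371 with an estimated correlation). The members that rose were mostly of class I: HLA-B by 1.45, whose reads can be shared between similar loci and are uncertain, beside the cathepsin gene CTSS by 2.58. This call ended with only genes of at least 5 FPKM (adjusted p = 0.107, range 9.12e-06 to 0.107 over 20 alternatives). Adjusting over each list alone left the counts of these 3 lists as they were.

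Genes of energy metabolism and epithelial junctions were mostly higher as well. All 13 mitochondrially encoded mRNAs were higher (median 0.99, camera adjusted p = 4.76e-05; adjusted p = 0.384 with an estimated correlation), with MT-ND4 rising by 1.16 (SE 0.07) and MT-ATP6 by 1.11 (SE 0.06); quantile normalization ended the call (adjusted p = 0.578, range 6.09e-10 to 0.578 over 20 alternatives), with 5 members higher and 3 lower. Glycolysis and hypoxia genes were higher in 16 of 22 cases and lower in 4 (median 0.45, camera adjusted p = 0.0225; adjusted p = 0.669 with an estimated correlation), and with equal FPKM sums 9 were higher and 6 lower (median 0.062). That median was 0.36 above the median of all genes in the same scaling, against 0.43 as deposited. The glycolysis and hypoxia call ended with only genes of at least 5 FPKM (camera adjusted p = 0.104, range 7.03e-04 to 0.104). The glycolytic genes HK1 and PFKP rose by 1.84 and 1.30, the hypoxia gene CA9 fell by 2.30 (SE 0.10), and the glucose transporter gene SLC2A1 fell by 1.66 (SE 0.09). Other hypoxia genes rose and another glycolytic gene fell, so these examples do not set glycolysis against hypoxia. Junction and epithelial genes had 14 of 18 members higher and 3 lower (median 0.36, camera adjusted p = 0.00713, and 0.425 with an estimated correlation). With libraries scaled to equal FPKM sums 7 were higher and 7 lower, at a median of −0.03 where all genes had −0.30. Relative to all genes the junction median was 0.27 in that scaling and 0.33 as deposited. The keratin gene KRT7 rose by 2.59 (SE 0.07), and KRT8, CLDN4 and KRT19, named after their values were seen, fell by 0.24, 0.24 and 0.18. KRT19 lost its call without GFP-positive replicate 1 or 3 (adjusted p = 0.0635 and 0.0524), without GFP-negative replicate 2 or 3 (0.0734 and 0.0818) and with no filter (0.0607), the other alternatives leaving it past the threshold. The junction call ended with only genes of at least 5 FPKM (adjusted p = 0.0543) and with quantile normalization (adjusted p = 0.241, range 3.51e-04 to 0.241). The counts of these lists did not move when adjusted over each list alone.

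**Figure D2:**
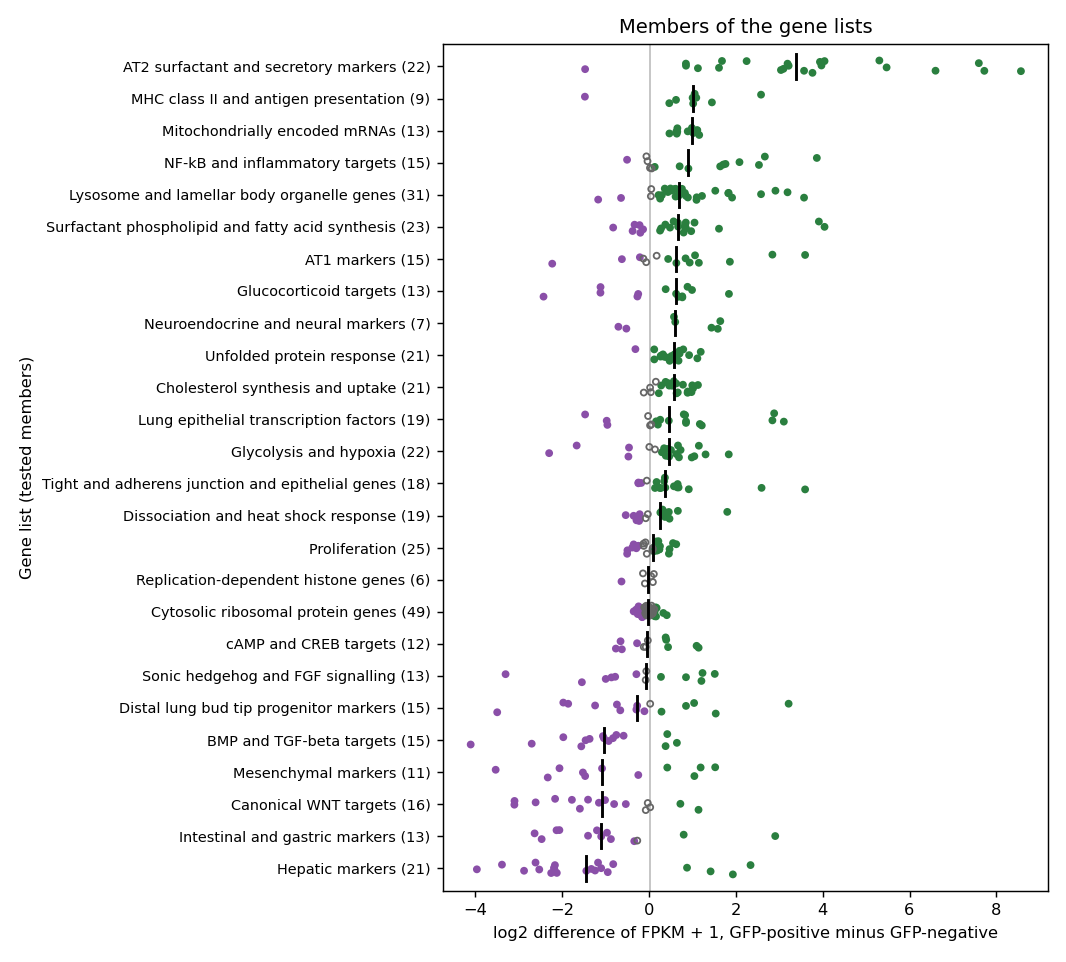
log2 difference of FPKM + 1, GFP-positive minus GFP-negative, of each tested member (point) of the 26 lists with at least 5 tested members; the vertical position within a list is arbitrary. Filled points had an adjusted p under 0.05 (green higher, purple lower), open points did not, black bars are list medians and the grey line is the median of all genes, 0.03; the AT2 markers have the highest median, 3.39, and the hepatic markers the lowest, −1.44.

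Most hepatic and intestinal markers were lower in GFP-positive cells. Of 21 hepatic markers, 17 were lower and 4 higher (median −1.44, camera adjusted p = 5.22e-05; adjusted p = 0.384 with an estimated correlation). AHSG fell by 3.96 (SE 0.16), the apolipoprotein genes APOA1 and APOB by 3.38 (SE 0.17) and 2.61 (SE 0.09), and the albumin gene ALB by 0.82 (SE 0.17), and the transferrin gene TF fell by 2.87 (SE 0.11). The 4 that rose were the fibrinogen chain genes FGG, from 31.1 ± 5.28 to 161 ± 15.9 FPKM, FGA (log2 difference 1.93) and FGB (0.88), and the transthyretin gene TTR (1.42); ALB and these 4 were named after their values were seen. Of 13 intestinal and gastric markers, 10 were lower and 2 higher (median −1.10, camera adjusted p = 0.00142; adjusted p = 0.259 with an estimated correlation). CDH17, the intestinal cadherin gene, fell by 2.63 (SE 0.12), CDX2 by 2.47 (SE 0.06) and LGALS4 by 2.13 (SE 0.08), whereas CEACAM5, an adhesion gene of mucosal epithelia, rose by 2.91 (SE 0.07) and TFF3, named after its value was seen, by 0.80. Scaling to equal FPKM sums ended the intestinal call (adjusted p = 0.102, range 6.70e-04 to 0.102 over 20 alternatives), although 11 members were then lower and 2 higher. The counts adjusted over each list alone were the same.

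Most targets of WNT, BMP and TGF-beta signalling were lower too. The activity of these pathways was not measured, and bulk values do not show in which cells a target differed. The WNT list shares members with the intestinal and tip progenitor lists. Among the BMP and TGF-beta targets, ID2 is also a tip progenitor marker and TAGLN a mesenchymal marker, so these results are not independent. Of 16 canonical WNT targets, 11 were lower and 2 higher (median −1.08, camera adjusted p = 1.42e-04; adjusted p = 0.252 with an estimated correlation). The transcription factor gene ASCL2 fell by 3.10 (SE 0.06), the secreted WNT inhibitor genes NOTUM and DKK1 by 3.09 (SE 0.11) and 2.61 (SE 0.05), and LEF1 by 2.16 (SE 0.06). CCND1 and MYC, which promote the cell cycle and were named after their values were seen, rose by 1.14 and 0.72. Of 15 BMP and TGF-beta targets, 12 were lower and 3 higher (median −1.04, camera adjusted p = 1.28e-04; adjusted p = 0.252 with an estimated correlation). BAMBI fell from 134 ± 7.64 to 6.86 ± 0.582 FPKM, and the BMP-induced ID4, ID2 and ID3 fell as well (−2.70, −1.97 and −1.56). The 3 that rose, named after their values were seen, were the TGF-beta targets TGFBI (0.64), TAGLN (0.42) and PMEPA1 (0.38); with equal FPKM sums TAGLN and PMEPA1 were at 0.15 each and did not pass. The list of hedgehog and FGF signalling did not pass (5 of 13 higher, 6 lower, camera adjusted p = 0.350). Among its members SHH, the hedgehog ligand gene, fell from 88.0 ± 4.03 to 8.04 ± 0.150 FPKM and FGFR3 by 1.54, while the FGF target DUSP6 rose by 1.52 and FGFR2, the receptor of keratinocyte growth factor, by 1.23. Mesenchymal markers had 4 of 11 members higher and 7 lower (median −1.08, camera adjusted p = 0.195); COL3A1, a fibrillar collagen gene, fell from 13.7 ± 2.42 to 0.270 ± 0.143 FPKM and LUM rose by 1.53. The counts of these 4 lists were the same when adjusted over each list alone.

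**Figure D3:**
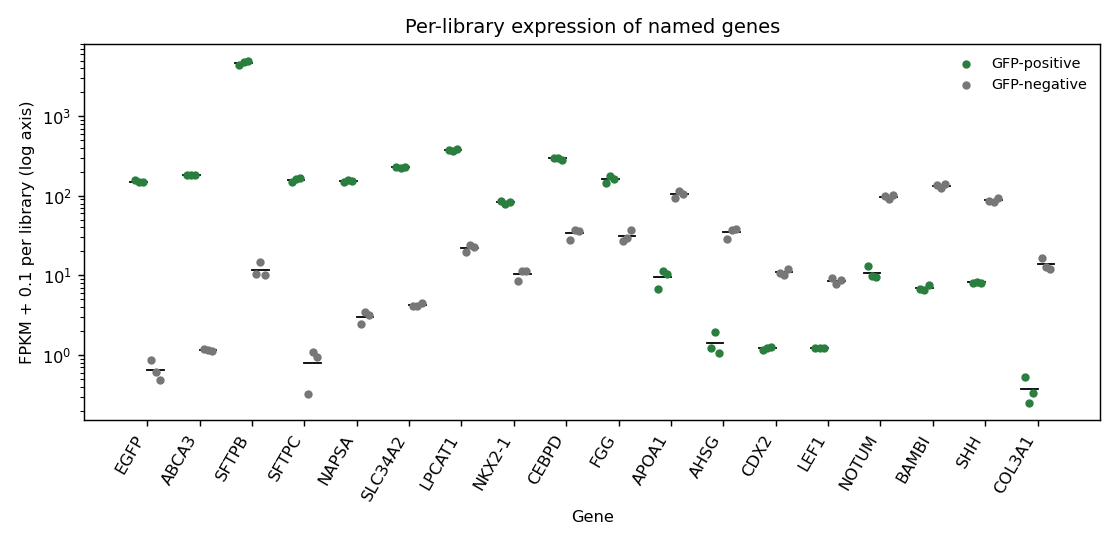
FPKM plus 0.1 of 18 named genes in each library (points) with the group mean (bar) on a logarithmic axis, GFP-positive in green and GFP-negative in grey, n = 3 each. The groups do not overlap for any of these genes; COL3A1, for example, averages 0.270 against 13.7 FPKM.

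The remaining lists did not pass as groups. Proliferation genes were higher in 12 of 25 cases and lower in 6 (14 and 6 when adjusted over the list alone; median 0.09, camera adjusted p = 0.605), and with equal FPKM sums 4 were higher and 19 lower. E2F1 and TOP2A rose by 0.63 and 0.55, the replication licensing genes MCM2 and MCM3 fell by 0.50 and 0.49, and the proliferation marker MKI67, named after its value was seen, was at 10.2 ± 0.242 against 10.9 ± 0.538 FPKM (adjusted p = 0.135). MKI67 passed as lower with equal FPKM sums (−0.45), recovered read totals (−0.31) and quantile normalization (−0.19). The median of all genes was −0.30, −0.18 and −0.02 in these settings. Glucocorticoid targets were higher in 8 of 13 cases and lower in 5 (camera adjusted p = 0.548; past the threshold with equal FPKM sums, adjusted p = 0.0311, range 0.0311 to 0.751 over 20 alternatives), with TSC22D3 rising by 1.84 and SLC19A3 falling by 2.43. Targets of cyclic AMP were higher in 5 of 12 cases and lower in 4 (camera adjusted p = 0.874; 3 and 7 with equal FPKM sums), with a median of −0.05 and a mean of 0.08; PDE4D rose by 1.14 and SIK1 fell by 0.76. Dissociation and heat shock genes, a sign of handling during the sort, were higher in 10 of 19 cases and lower in 7 (camera adjusted p = 0.658); with equal FPKM sums 2 were higher and 10 lower. SOCS3 rose by 1.80, FOSB fell by 0.53 and FOS was at 229 ± 13.3 against 241 ± 12.4 FPKM (adjusted p = 0.270). FOS passed as lower with equal FPKM sums (−0.47), recovered read totals (−0.33) and quantile normalization (−0.34), beside the same medians of all genes of −0.30, −0.18 and −0.02. Of 7 neuroendocrine markers, 5 were higher and 2 lower (camera adjusted p = 0.153), with UCHL1 rising by 1.64; the list passed as higher with equal FPKM sums (adjusted p = 0.00265) and with recovered read totals (0.0123), in a range of 0.00265 to 0.786 over 19 alternatives. For the glucocorticoid, cyclic AMP, dissociation and neuroendocrine lists the counts were the same when adjusted over each list alone.

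Of 49 cytosolic ribosomal protein genes, 8 were higher and 16 lower (7 and 15 when adjusted over the list alone; median −0.03, camera adjusted p = 0.280). With equal FPKM sums 0 were higher and 47 lower, at −0.13 relative to all genes, and the list passed (adjusted p = 3.20e-05), as it did with recovered read totals (1.03e-04), with quantile normalization (1.36e-08) and without GFP-negative replicate 1 (adjusted p = 0.0406, range 1.36e-08 to 0.572 over 20 alternatives). RPS16 rose by 0.41, which became 0.01 and did not pass with equal FPKM sums, and RPL6 fell by 0.35. Of 6 replication-dependent histone genes, 1 passed, HIST1H1C (−0.65), also when adjusted over the list alone (camera adjusted p = 0.565). The other 4 lists had too few tested members for a group test, and their counts were the same when adjusted over each list alone. Of 3 airway markers tested, the secretoglobin gene SCGB3A2 rose from 0.0115 ± 0.0101 to 14.0 ± 2.36 FPKM, the ciliated cell factor FOXJ1 fell by 1.32 and TPPP3 rose by 0.31 (adjusted p = 0.0230); TPPP3 lost its call without GFP-positive replicate 2 (0.0604) and without GFP-negative replicate 1 or 3 (0.0579 and 0.0641), as with quantile normalization, array weights and recovered read totals, and turned to −0.076 with equal FPKM sums. Of 4 pluripotency markers tested, LIN28A, SALL4 and DNMT3B fell by 2.84, 1.10 and 0.81 and ZFP42 rose by 0.29, a call lost with equal FPKM sums (0.088) and with recovered read totals (0.16). The lysozyme gene LYZ, the 1 tested marker of the endothelial and blood list, fell by 3.21 (SE 0.07), and HHEX, the 1 tested marker of thyroid and other anterior foregut, did not pass (0.01, adjusted p = 0.845) and turned lower with equal FPKM sums (−0.32) and with recovered read totals (−0.20).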

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

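Scaling to the recovered read totals and voom on the recovered reads were chosen after the data were seen, and the other settings before. ABCA3 kept its call under every alternative, with a log2 difference of 6.19 to 7.44, and of 148 named genes 134 kept direction and call under every alternative run. How many genes counted as higher or lower depended most on scaling: equal FPKM sums gave 2110 higher and 8678 lower, and recovered read totals 2847 and 7135, against 4929 and 4129 as deposited. Both shift the median of all genes by construction, to −0.30 and −0.18. Median of ratios scaling gave 5067 higher and 4050 lower, and quantile normalization 4269 and 4846. With equal FPKM sums and recovered read totals HMGCS1 turned to −0.35 and −0.21, HHEX to −0.32 and −0.20 and EEF1A1 to −0.37 and −0.23. TPPP3 turned to −0.076 with equal FPKM sums. Quantile normalization put HMGCS1 at −0.24 and EEF1A1 at −0.91; the cause was not tested. A minimum of 5 FPKM left fewer genes to test, 7486, of which 2110 were lower and 854 changed at least 2-fold. It left 7 lists higher. The junction list lost its call although all of its 18 tested members were kept, so a loss of members cannot explain that list. The median log2 difference of all genes was 0.09 in this setting, and why lists lost their call was not tested. Without a filter the first principal component held 85.9% of the variance, since genes near 0 entered. Of the lists, 11 were higher and 4 lower by camera at its preset correlation, 0 and 0 with an estimated correlation (smallest adjusted p = 0.252) and 17 and 7 by fry, which tests no list against other genes; fry turned the cyclic AMP list to higher (adjusted p = 3.01e-04, against 0.385 to 0.983 over the 20 alternatives at the preset correlation). Leaving out each library in turn gave 4580 to 4795 genes higher, 3712 to 4022 lower and 1378 to 1427 genes changed at least 2-fold. The fit with a replicate block gave 4911 higher and 4070 lower and an ABCA3 difference of 6.49, and changed no call of a named gene or list except that FTL passed as lower (−0.16). Deviations of same-numbered libraries correlated by 0.10, 0.07 and −0.02 and 2 of 3 GFP-positive libraries correlated best with their own number, so the numbers were not taken to pair the samples. Depth limits genes of few reads: 1 read on 1 kb was worth 0.0171 to 0.0219 FPKM.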

Other observations

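The family scan and the tests of carry-over, of a lower NKX2-1 level, of both kinds of scaling and of hepatic-like cells were chosen after the results were seen, and the genes of this paragraph and the next, other than COL3A1, COL5A1 and TWIST1, were named after their values were seen, as were EEF1A1, FTL, HP and ORM1. In a scan of 150 families of genes with a shared symbol stem and at least 8 tested members, 7 passed camera, 4 higher and 3 lower, and none passed with an estimated correlation (adjusted p from 0.285 to 0.858 with an estimated correlation). The HOXA stem, with 7 homeobox genes that pattern the body axis and 1 antisense transcript, fell in 8 of 8 tested genes (median −1.51, camera adjusted p = 4.33e-04; adjusted p = 0.858 with an estimated correlation), under each of the 4 other scalings as well. HOXA5 stood at 0.0803 ± 0.0699 FPKM in GFP-positive and 3.58 ± 0.277 in GFP-negative cells, and HOXA13, a posterior member, at 0.0279 ± 0.0142 against 3.36 ± 0.0807 (SD, n = 3 each). HOXB9 fell by 3.56 (SE 0.06) on the log2 scale, TBX4, a transcription factor gene of lung and hindlimb mesenchyme, fell by 3.76 (SE 0.06), and PITX1, a hindlimb factor, fell by 3.72 (SE 0.08). Of the mesenchymal markers, which as a list did not pass (camera adjusted p = 0.195), 7 of 11 fell and 4 rose, with COL3A1 at −3.53, COL5A1 at −2.33 and TWIST1 at −2.06 (0.0138 against 3.46 FPKM), and VIM at 1.19. The zinc finger genes of the ZNF stem were lower in 230 of 377 cases and higher in 42 (median −0.21, camera adjusted p = 4.09e-06, and adjusted p = 0.285 with an estimated correlation). With equal FPKM sums 336 were lower and 3 higher, at a median of −0.19 relative to that of all genes. The MCM stem, mostly genes of replication licensing, was lower in 8 of 9 cases and higher in 0 (median −0.35, camera adjusted p = 0.0303; adjusted p = 0.858 with an estimated correlation), whereas the proliferation list as a whole did not pass.

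Families of the secretory route and of organelle acidification, with the stems ATP6V, SEC and TMED, were mostly higher. All 14 tested subunit genes of the vacuolar proton pump (ATP6V) rose (median 0.49, camera adjusted p = 5.29e-04; adjusted p = 0.858 with an estimated correlation), ATP6V1D by 0.98 (SE 0.03) and ATP6V0D1 by 0.90 (SE 0.04); with equal FPKM sums 7 were higher and 1 lower, at a median of 0.39 above that of all genes. Genes of the SEC stem, most of them of the translocon and of vesicle coats, were higher in 20 of 25 cases and lower in 3 (camera adjusted p = 0.0303; adjusted p = 0.858 with an estimated correlation), and in 8 and 7 with equal FPKM sums. The median of the SEC stem was 0.32 above that of all genes both as deposited and with equal FPKM sums. SEC24D, a coat protein gene of vesicles leaving the endoplasmic reticulum, rose by 1.04 (SE 0.06), and SEC61A1, the translocon channel gene, by 0.68 (SE 0.04). Of the 9 cargo receptor genes of the TMED stem, 8 rose (camera adjusted p = 0.0382; adjusted p = 0.858 with an estimated correlation), TMED2 by 0.76 (SE 0.04), and with equal FPKM sums 5 were higher and 2 lower. The palmitoyltransferase genes of the ZDHHC stem were higher in 13 of 18 cases and lower in 1 (camera adjusted p = 0.0342; adjusted p = 0.858 with an estimated correlation), and in 6 and 7 with equal FPKM sums. The ZDHHC median was 0.33 above that of all genes as deposited and 0.31 above it with equal FPKM sums. The 3 next-largest rises after the 10 named by the rule were of RNASE1 (209 ± 15.6 against 6.45 ± 1.05 FPKM), the aquaporin gene AQP3 (80.0 ± 1.66 against 2.44 ± 0.319) and WFDC2 (411 ± 35.7 against 17.0 ± 1.76). Beside ABCA3, a noncoding gene on the opposite strand (ENSG00000260778, chromosome 16, 2268155 to 2273418), whose nearer end lies 2463 bp beyond the 3' end of ABCA3, held 854 reads in GFP-positive and 45 in GFP-negative libraries.

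NKX2-1 in the GFP-negative libraries was left at 12.6% ± 2.03 of its mean GFP-positive level (SD, n = 3), with PGC at 12.2% and CEBPD at 11.4%, while EGFP was left at 0.362% ± 0.126 and SFTPC at 0.434%. Reporter-positive cells carried into the negative sort would leave each gene at about the same percent. The percent left of NKX2-1 was 34.8 times that of EGFP, and the lowest NKX2-1 library (10.3%) lay above the highest EGFP library (0.50%), which argues against carry-over as the whole source. GFP-negative cells that express NKX2-1 at a lower level, or in a part of the cells, would leave it above the surfactant protein genes, and it was left at 43.3 times their median of 0.291%. This is consistent with that hypothesis, found and tested on the same data, and bulk values cannot separate a low level in all cells from a high level in a few.

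All 13 mitochondrially encoded mRNAs were higher in GFP-positive cells, by a median of 0.96 above that of all genes (0.83 to 1.08 over the 9 pairings of libraries), which argues against a single scaling factor per library as the whole cause, since that moves all genes alike. Camera had already called these mRNAs against the other genes, so the excess was part of the pattern and is no separate test of that explanation. Quantile normalization, which fixes the values of the highest ranks where these mRNAs lie, left an excess of 0.058. Of the 4 nuclear genes at their expression levels, EEF1A1 (0.03) and FTL (−0.16, but past the threshold as lower under 9 of 20 alternatives, among them without GFP-negative replicate 1 at −0.21) did not pass and SFTPB and PGC rose, which runs in part against a scaling that depends on expression level but is too few genes to exclude it. A general rise of the respiratory chain was tested on its nuclear-encoded subunits, of which 54 of 73 were higher and 5 lower, by a median of 0.26 above all genes (0.18 to 0.33 over the 9 pairings of libraries; camera p = 2.71e-06, and p = 0.314 with an estimated correlation). The median excess of 0.26 fell short of the 0.30 set before the test, which by that rule counts against a general rise. The spread over the pairings, which the rule did not include, reaches 0.33, so a general rise may contribute and stays open. A difference in mitochondrial RNA per cell and the sort itself were not tested and stay open as well.

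The fibrinogen genes rose while 17 of 21 hepatic markers fell. Hepatic-like cells in the GFP-positive sort would bring the other hepatic genes along, but these had a median log2 difference of −2.14 (−2.24 to −1.84 over the 9 pairings of libraries, 18 genes). This fall was already part of the pattern, so it is no separate test of that explanation. It shows that the other hepatic genes did not rise as a set, and lower levels do not show that such cells were absent. An acute phase response would raise the other acute phase genes: 6 of 10 tested were higher and 4 lower, among them the haptoglobin gene HP at 1.55 and the orosomucoid gene ORM1 at −1.09 (camera p = 0.422, and p = 0.709 with an estimated correlation). Members that go both ways leave an acute phase response open, and no biological explanation specific to fibrinogen was tested.

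Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many genes as the real split, the real split itself, with 9058 genes against at most 0 for the others (limma; at an unadjusted p under 0.05 the real split had 9476 genes and the others 69 to 105). With 10 splits the share cannot fall under 0.05. Every other split also mixes both populations in each of its groups, so the population difference adds to the spread within groups. Few calls could then be expected, and the other splits give no measure of chance.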
